A study of Mus musculus with 6 samples.

How the data were processed

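CD8+ T cells were profiled by bulk RNA sequencing of 3 WT and 3 Zfp335-deficient libraries, sorted on day 7 after infection from recipients of both kinds of cells. Per the labels' protocols, total RNA was extracted with a column kit, its quality was checked by gel and Bioanalyzer, and libraries were made from 200 ng of total RNA with the TruSeq RNA kit of Illumina. The kit's strand setting is not given in the sources used here, so a gene and an overlapping antisense gene cannot be told apart. The mice were of strain C57BL/6, per the labels.

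The authors deposited a single table of estimated read counts per gene symbol, with a column per library. Per the submitters' processing notes, Trim Galore 0.5.0, cutadapt 1.15 and DESeq2 (no version named) were used with the mm10 genome build. The aligner, the quantifier and the annotation are not given in the sources used here. The deposited values are estimated counts and not whole counts, since 56.9% to 59.9% of values in a library lie within 0.005 of a whole number, and they were not scaled, since the library totals differ. The table has 12252 lines with 12230 unique symbols. The lowest sum over the 6 libraries is 59.6, so genes with fewer counts had been left out before deposition. The 22 symbols found on more than 1 line were kept as separate entries. Each column was assigned to a library by the genotype and number in its name. The analysis had been planned for whole counts, and the estimated counts were rounded to whole numbers first.

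Library totals were 43922867, 40914781 and 39448347 in WT 1, 2 and 3 and 36327126, 40397301 and 38102328 in Zfp335-deficient 1, 2 and 3, and the 20 most abundant genes held 8.41% to 9.3% of the counts. Precision was limited by the spread between libraries, with a common biological coefficient of variation of 9.91%, more than by depth.

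Gene counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr by group, which left 12219 and removed 33. TMM normalization, robust dispersion estimation (estimateDisp) and robust quasi-likelihood fits (glmQLFit, glmQLFTest) were used with genotype as the only term. Tests were two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05 on the adjusted p. Log2 fold changes are Zfp335-deficient over WT, and their standard errors were computed as the fold change divided by the square root of the F statistic. CPM values use TMM-scaled library sizes, and values after ± are SDs over 3 libraries for CPM and SEs for log2 fold changes. Adjusted p-values of genes are from this edgeR test.

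Before the data were examined, 17 lists of T cell biology, 8 lists of markers of other cell types and a list of immediate-early and heat-shock genes were fixed, together with the rule for named genes, the design and most alternatives. Lists with at least 5 tested genes (3 for the other-cell and handling lists) were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment within each of both families of lists, and again with an estimated correlation and with fry. The named genes were Zfp335, 12 key genes, the up to 4 members of each list with the smallest p-value, and the 10 largest rises and 10 largest falls. The last were taken among genes with an adjusted p under 0.05, a mean log2 CPM of at least 3 and no overlap between the genotypes, leaving out unnamed clones, pseudogenes and receptor segments. A few genes that this rule selects are not reported here. Other list members and the gene copies named in the text were chosen after their values were seen. A list of plasma-cell markers was added after the data were seen. The symbols of mitochondrial genes in the lists were matched to those in the table (ND3 for mt-Nd3).

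Positions, transcript lengths and GC content came from GENCODE M21 (GRCm38, which is mm10), matched by symbol for 11948 genes and through older symbols for 174 more, 99.1% in all. Replicates were compared by a chi-square test of their counts over genes with at least 20 counts in a pair, and by principal components of log2 CPM.

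The alternatives set beforehand were RLE and upper-quartile scaling, no filter and a stricter filter (CPM of at least 5 in 3 libraries), a replicate block, each library left out in turn, receptor-segment, haemoglobin and mitochondrial genes left out, fits without robust estimation, DESeq2 1.42.0, limma-voom, a test against a 1.5-fold change, an adjusted p threshold of 0.01, and the other list tests. Chosen after seeing the data were a per-library loess correction (span 0.5) for transcript length and GC content, with and without Zfp335-deficient replicate 3, and the removal of genes in 5 Mb bins with an excess of changes of at least 2-fold, found with a hypergeometric test over 378 bins.

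The edgeR step was tested on simulated data for the comparison of Zfp335-deficient with WT cells, with 12165 genes in the fit. It recovered 10% of genes changed 1.25-fold, 70.8% of those changed 1.5-fold, 89.8% of those changed 2-fold and 96% of those changed 4-fold, and it called 4 of 11968 unchanged genes. Simulated counts were drawn independently for each gene and library. They hold no deviation shared by genes, such as a trend with transcript length in a single library, so error rates in the real data may differ.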

Results

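RNA of wild-type (WT) and Zfp335-deficient CD8+ T cells was measured by sequencing. Zfp335 is a zinc-finger transcription factor. Cells of both genotypes had been given together to recipient mice, which were then infected with LM-OVA, a strain of the bacterium Listeria monocytogenes that expresses ovalbumin. Splenic CD8+ T cells of each genotype were sorted on day 7 after infection. The title of the series names memory CD8+ T cells and TCF-1, the transcription factor encoded by Tcf7, as the subject of the study. Each genotype had 3 libraries, and the estimated gene counts summed to 36327126 to 43922867 per library. Whether the 3 libraries of a genotype came from separate recipients is not stated in the labels, so the p-values measure the spread between these libraries, which may be partly technical.

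The genotypes separated along the first principal component, which held 63.7% of the variance. WT libraries lay close to each other, with a chi-square statistic per gene of 3.87 to 8.68 in their pairwise comparisons, where counting noise alone gives 1. Zfp335-deficient replicates 1 and 2 were as close, at 8.06, and no pair was near enough to be the same library deposited again. Zfp335-deficient replicate 3 stood apart from its own group, at 76.5 and 68.6 against replicates 1 and 2, and on the second principal component, which held 18.1% of the variance. Its deviation followed transcript length. Relative to replicates 1 and 2 it was higher by a median of 0.23 on the log2 scale in the quintile of genes with the shortest transcripts. In the quintile with the longest it was lower, with a median of -0.33. Across 12105 genes, which are not independent replicates, Spearman's rho between this deviation and transcript length was -0.515, and it was -0.052 for the difference between replicates 2 and 1. The difference between the genotypes followed transcript length too, with a rho of -0.236 with all libraries and 0.016 without Zfp335-deficient replicate 3. Against the mean of WT the values were 0.026, -0.006 and -0.43 for Zfp335-deficient replicates 1, 2 and 3.

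**Figure D1:**
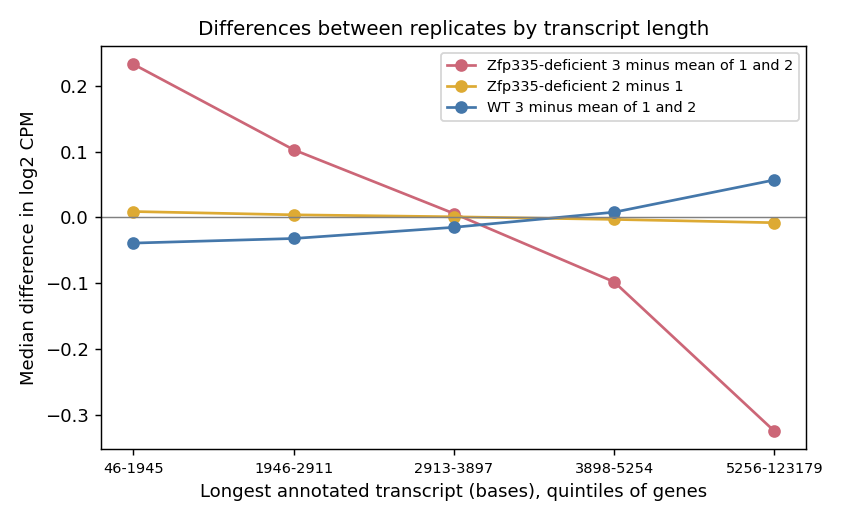
Median difference in log2 CPM between libraries, over quintiles of genes ordered by the length of their longest annotated transcript in bases. Points joined by lines are Zfp335-deficient replicate 3 minus the mean of replicates 1 and 2, Zfp335-deficient replicate 2 minus 1, and WT replicate 3 minus the mean of WT 1 and 2; the first falls from 0.23 to -0.33, and the others stay between -0.04 and 0.06.

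Zfp335 transcripts, the targeted gene (chromosome 2, 164891882 to 164911757, minus strand, mm10), were lower in all 3 libraries labelled Zfp335-deficient. The mean was 118 ± 1.58 CPM in WT and 73.5 ± 3.91 CPM in Zfp335-deficient cells (SD, n = 3 each), a log2 fold change of -0.68 ± 0.06 (SE; adjusted p = 0.000397, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The transcript was thus reduced 1.6-fold in counts over the whole gene. Which exons the mutation removes is not given in the sources used here, and counts per gene include reads from any exons that remain.

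Between the genotypes 1622 of the 12219 genes tested differed, 983 higher and 639 lower in Zfp335-deficient cells. Of these, 374 differed at least 2-fold, 222 higher and 152 lower. Among the largest falls were Ctse, which encodes the aspartic protease cathepsin E (319 ± 3.91 CPM in WT and 17.6 ± 0.23 CPM in Zfp335-deficient cells, n = 3 each), and Bmf, a pro-apoptotic BH3-only gene (16.6 ± 1.17 and 0.297 ± 0.0666 CPM). Baiap3, a regulator of vesicle exocytosis, fell from 645 ± 7.61 to 3.26 ± 0.742 CPM. The tripartite-motif genes Trim16 and Mid1 had log2 fold changes of -3.61 ± 0.07 and -3.21 ± 0.07. Esr1, the gene of oestrogen receptor alpha, rose from 0.586 ± 0.161 to 34.8 ± 1.41 CPM, and Xkr6 from 0.46 ± 0.122 to 18.4 ± 0.73 CPM. The count of changed genes depended on single libraries, being 4112 (2122 higher, 1990 lower) without Zfp335-deficient replicate 3 and 824, 805 and 810 without WT replicate 1, 2 and 3. With a correction for transcript length and GC content and without Zfp335-deficient replicate 3 it was 4608 (2287 higher, 2321 lower).

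The remaining genes with the largest falls by the naming rule were Eps8l1 (5922 counts summed over the 3 WT libraries and 13 over the 3 Zfp335-deficient libraries), Ptprv (log2 fold change -3.37), Med12l (-3.30), Eif3j1 (-3.29) and Tanc1 (-3.01). Those with the largest rises were Hmga1b (5 counts summed over WT and 7912 over Zfp335-deficient libraries), Rpl29 (log2 fold change 4.48), Izumo4 (2.78), the receptor tyrosine kinase gene Ltk (2.76), Btbd11 (2.47), the calmodulin-dependent kinase gene Camk2b (2.36), the mitochondrial gene ND3 (2.33) and Rsph3b (4.49 ± 0.974 CPM in WT and 18 ± 3.42 CPM in Zfp335-deficient cells). All 20 genes passed the same test, with adjusted p from 4.61e-08 (Ctse) to 0.000676 (ND3). Several are uncertain because reads can be shared with a near-identical copy, and the copies moved apart. Hmga1 fell (-1.13 ± 0.09) where Hmga1b rose, and Eif3j2 rose (1.45 ± 0.06) where Eif3j1 fell. From WT to Zfp335-deficient cells, Hmga1 went from 105 ± 3.99 to 48.2 ± 5.33 CPM and Hmga1b from 0.0378 ± 0.0655 to 69.3 ± 9.36 CPM. Eif3j1 went from 49.3 ± 1.86 to 5.06 ± 0.84 CPM and Eif3j2 from 28.2 ± 0.451 to 77 ± 0.573 CPM. Within each pair the fall and the rise were of similar size, so reads assigned to the other copy could account for much of both, which was not tested. The ribosomal-protein gene Rpl29 has many processed copies in the genome. Izumo4 and Eif3j1 lay in 2 of the 3 stretches of 5 Mb in which changes of at least 2-fold were over-represented, and Bmf, Ltk and Btbd11 lay within 2 Mb of such a stretch. Med12l, Baiap3, Eps8l1, Ctse and Trim16 lay in stretches whose excess did not pass adjustment (unadjusted p 0.0102 to 0.0435, adjusted p 0.385 to 0.866, hypergeometric test). Each such count includes the named gene itself, so these values do not settle whether its change is part of a wider stretch.

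The genes that mark memory and effector differentiation went both ways. Tcf7 (chromosome 11, 52252371 to 52283014, minus strand) fell from 181 ± 0.674 to 123 ± 4.31 CPM (n = 3 each), a log2 fold change of -0.56 ± 0.06 (adjusted p = 0.000536, edgeR's quasi-likelihood test). Slamf6, a surface receptor used to mark TCF-1-positive cells, fell with it (-0.45 ± 0.05), as did the ecto-nucleotidase gene Nt5e (-0.47) and Klf2 (-0.36), a regulator of T cell trafficking. Id3, an inhibitor of E-protein transcription factors associated with memory precursors, rose (0.83 ± 0.12), at levels of 3.16 ± 0.2 and 5.61 ± 0.564 CPM, and Dapl1 rose by 1.24 ± 0.18. Of the 25 memory-precursor and central-memory genes, 5 were lower, 2 higher and 18 did not pass (8 and 4 passed when adjusted over the list alone). The list had a median log2 fold change of -0.13. In camera, a test of whether a list moves relative to the other genes, its adjusted p was 0.228. Without Zfp335-deficient replicate 3, 9 were lower and 8 higher, and without any other library 3 and 2.

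Il7r, the interleukin-7 receptor gene, had a log2 fold change of 0.17 ± 0.07 (adjusted p = 0.175, edgeR's quasi-likelihood test) and did not pass. Without Zfp335-deficient replicate 3 it passed, with an adjusted p of 0.000369, within a range of 0.000185 to 0.443 over all alternatives. The survival gene Bcl2 had a value of -0.30 ± 0.08 (adjusted p = 0.0545), which became 0.00037 without that replicate (range over alternatives 6.52e-05 to 0.195). Eomes (-0.10 ± 0.06, adjusted p = 0.345) and Tbx21, the gene of T-bet (0.12 ± 0.09, adjusted p = 0.407), passed under no setting tried.

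**Figure D2:**
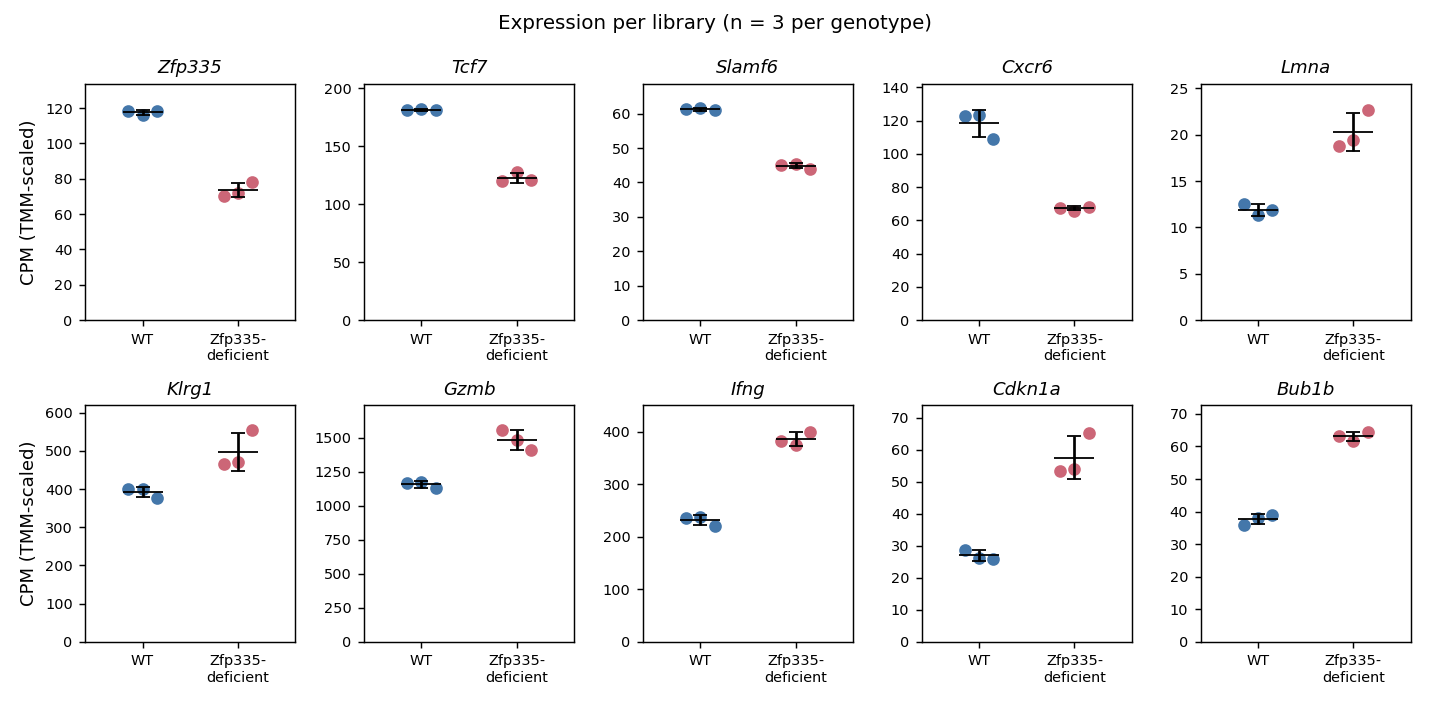
TMM-scaled CPM of 10 genes in each of the 3 WT and 3 Zfp335-deficient libraries (points), with the mean (horizontal line) and SD (error bar) of each genotype, on axes that start at 0. For Zfp335, Tcf7, Slamf6 and Cxcr6 every Zfp335-deficient library lies below every WT library, and for the other genes every Zfp335-deficient library lies above.

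Klrg1, a lectin-like receptor of short-lived effector cells, rose from 392 ± 13.7 to 497 ± 49.6 CPM (log2 fold change 0.34 ± 0.08, adjusted p = 0.0295, edgeR's quasi-likelihood test), and Bhlhe40, a transcription factor of activated T cells, rose by 0.47 ± 0.06. Id2, a regulator of effector differentiation, fell (-0.28 ± 0.07, adjusted p = 0.0414), and so did the chemokine receptor gene Cx3cr1 (-0.36 ± 0.06). Of the annexin genes, Anxa1 fell (-0.73 ± 0.09) and Anxa2 rose (0.44 ± 0.08). Of the 30 terminal-effector surface and regulator genes, 6 were higher, 5 lower and 19 did not pass (7 and 7 passed when adjusted over the list alone). The list had a median of 0.07 and a camera adjusted p of 0.808, and 13 members were higher and 9 lower without Zfp335-deficient replicate 3. Without WT replicate 1, 2 or 3 these numbered 1, 2 and 1 higher and 2, 1 and 1 lower. The calls for Klrg1 and Id2 were lost when any WT library or Zfp335-deficient replicate 2 was left out, and that for Id2 also without Zfp335-deficient replicate 1, with adjusted p up to 0.141 and 0.172. Over all alternatives these ranged from 2.72e-08 to 0.141 and from 1.61e-07 to 0.172. Without WT replicate 2 or 3 Cx3cr1 and Anxa2 were not called either, nor was Anxa2 without WT replicate 1 (ranges over all alternatives 4.67e-10 to 0.0573 and 7.96e-11 to 0.0697).

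Several cytotoxic granule and effector cytokine genes were higher in Zfp335-deficient cells. Ifng, the interferon-gamma gene, rose from 232 ± 8.99 to 386 ± 13.3 CPM (log2 fold change 0.74 ± 0.06, adjusted p = 0.000206, edgeR's quasi-likelihood test), and the chemokine genes Ccl4 and Ccl3 rose by 1.02 ± 0.08 and 0.86 ± 0.07. Gzmb, the granzyme B gene, rose from 1157 ± 24.9 to 1482 ± 75.3 CPM (0.36 ± 0.06, adjusted p = 0.00825), a call lost without WT replicate 1, 2 or 3 (adjusted p = 0.0532, 0.0521 and 0.061; range over all alternatives 3.2e-12 to 0.061). Xcl1 (1.14), Tnf (0.65) and Fasl (0.29) were also higher. Of 22 members tested, 9 were higher, 1 was lower and 12 did not pass (10 and 2 passed when adjusted over the list alone). Without WT replicate 1, 2 or 3 only 5 were higher, and 3 were lower without Zfp335-deficient replicate 3. The exception, Gzmm (chromosome 10, 79689020 to 79695261), which encodes granzyme M, fell from 96.6 ± 0.974 to 25.5 ± 5.04 CPM and starts just below one of the stretches of 5 Mb with over-represented large changes. The list's camera adjusted p was 0.00413, and with an estimated correlation between genes the adjusted p was 0.474.

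Immediate-early genes, which respond within minutes to receptor signals and to cell handling, were higher in the same libraries. Egr1 rose from 94.5 ± 1.81 to 206 ± 16.2 CPM (log2 fold change 1.12 ± 0.07, adjusted p = 6.97e-05, edgeR's quasi-likelihood test), Atf3 by 1.13 ± 0.09, Jun by 0.65 ± 0.05 and Dusp1 by 0.62 ± 0.05, whereas the heat-shock genes Hspa1b (-0.58) and Hspa1a (-0.37) fell. Of the 14 genes of this list, fixed as a sign of handling, 10 were higher and 2 lower (11 and 2 when adjusted over the list alone), and their summed expression was 3104 ± 86 CPM in WT and 4288 ± 213 CPM in Zfp335-deficient cells. Camera gave an adjusted p of 2.96e-06, and the adjusted p was 0.0453 with an estimated correlation. The latter call was lost with any 1 library left out (0.0534 to 0.132; range over 15 alternatives 0.0336 to 0.303).

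Among inhibitory-receptor and exhaustion-linked genes, Nr4a1 and Nr4a2, immediate-early nuclear receptors, rose by 0.67 ± 0.05 and 0.88 ± 0.17, Lag3 rose by 0.56 ± 0.11, and Btla fell (-0.46 ± 0.12). Of 17 members, 4 were higher, 1 was lower and 12 did not pass (6 and 1 passed when adjusted over the list alone). Without WT replicate 2 or 3 the calls for Lag3, Nr4a2 and Btla were lost, and 1 member was higher; those for Nr4a2 and Btla were also lost without WT replicate 1 or Zfp335-deficient replicate 2. Adjusted p of these 3 genes ranged over all alternatives from 1.28e-06 to 0.0707, 5.52e-21 to 0.0729 and 0.000472 to 0.148. Camera gave an adjusted p of 0.186. Without Zfp335-deficient replicate 3 the list passed, with 6 higher, 3 lower and an adjusted p of 0.00361 (camera range over 15 alternatives 0.00228 to 0.269), and it passed with fry (0.00305). Of the adhesion and chemokine-receptor genes, the chemokine receptor gene Cxcr6 fell from 118 ± 7.95 to 67.3 ± 1.24 CPM (-0.81 ± 0.07, adjusted p = 0.000256, edgeR's quasi-likelihood test). The early activation gene Cd69 rose (0.61 ± 0.06), as did Icam1 (0.45 ± 0.06) and Cxcr4 (0.77 ± 0.11). In that list 3 of 19 were higher and 1 was lower (3 and 2 when adjusted over the list alone; 4 and 5 without Zfp335-deficient replicate 3, 2 lower without WT replicate 2). The camera adjusted p was 0.808, and the median (0.01) and mean (-0.02) had opposite signs. Of 21 T cell receptor complex and proximal signalling genes, the receptor constant gene Trbc2 rose (0.70 ± 0.10), Cd6 fell (-0.35 ± 0.08) and 19 did not pass, with the same counts when adjusted over the list alone. Without Zfp335-deficient replicate 3, 7 were lower and 2 higher, and the Cd6 call was lost without any other library (adjusted p up to 0.115; range over all alternatives 9.06e-14 to 0.115). The camera adjusted p was 0.808, with a median of -0.01 and a mean of 0.00, and Nfatc1 (-0.17 ± 0.07) and Cd8a (-0.11 ± 0.06) were among the members that did not pass. Both passed without Zfp335-deficient replicate 3, at 0.0145 and 0.00651 (ranges over all alternatives 0.0145 to 0.405 and 0.000132 to 0.552).

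Cell-cycle genes that passed were all higher in Zfp335-deficient cells. Of the 28 mitotic genes, 20 were higher, none was lower and 8 did not pass (22 higher when adjusted over the list alone), with a median log2 fold change of 0.41. The spindle-checkpoint kinase gene Bub1b, which lies within 2 Mb of the stretch on chromosome 2 with over-represented large changes, rose from 37.6 ± 1.49 to 63.1 ± 1.48 CPM (0.75 ± 0.06, adjusted p = 0.000218, edgeR's quasi-likelihood test), cyclin A2 (Ccna2) by 0.57 ± 0.06, survivin (Birc5) by 0.56 ± 0.06 and the kinase gene Aurka by 0.60 ± 0.07. The list's camera adjusted p was 7.61e-10, and with an estimated correlation the adjusted p was 0.0777. With that correlation it passed without Zfp335-deficient replicate 3, at 0.0476 (range over 15 alternatives 0.0185 to 0.457). Of the 28 DNA-replication and S-phase genes, 18 were higher, none was lower and 10 did not pass (23 higher when adjusted over the list alone), with a median of 0.34. Rrm1, the large subunit of ribonucleotide reductase, rose by 0.51 ± 0.06 and the primase gene Prim1 by 0.66 ± 0.08. Uhrf1, which recruits DNA methylation to replicated DNA, rose by 0.38 ± 0.05, and the chromatin-assembly gene Chaf1a by 0.42 ± 0.06. The camera adjusted p was 1.3e-06, and with an estimated correlation the adjusted p was 0.149. With 1 library left out, 14 (without WT 1 or 2) to 27 (without Zfp335-deficient 3) mitotic and 6 (without WT 1, 2 or 3) to 24 (without Zfp335-deficient 3) S-phase genes were higher and none was lower.

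**Figure D3:**
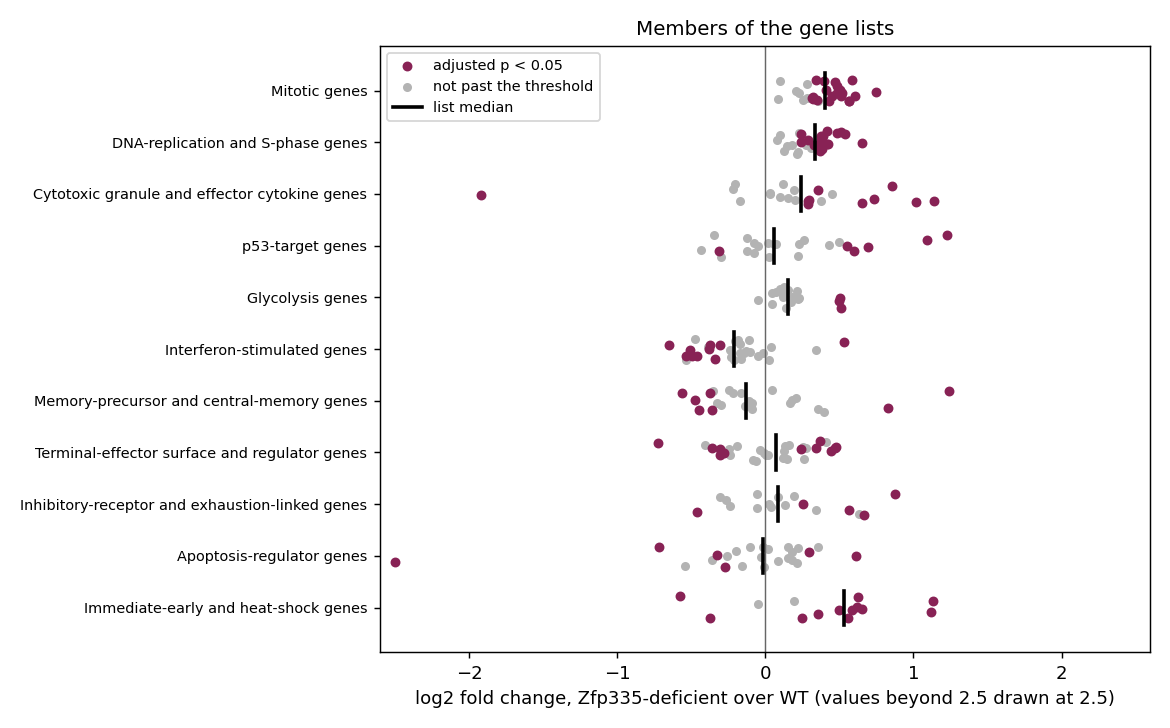
Log2 fold change, Zfp335-deficient over WT, of each member of 11 gene lists; red points passed the adjusted p threshold of 0.05, grey points did not, and black bars are list medians, which are 0.41 for mitotic, 0.34 for S-phase and -0.21 for interferon-stimulated genes. Values beyond 2.5 are drawn at 2.5, which applies to Bmf among the apoptosis regulators.

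Among targets of the tumour suppressor p53, Cdkn1a, the gene of the cell-cycle inhibitor p21, rose from 27 ± 1.61 to 57.5 ± 6.61 CPM (1.09 ± 0.09, adjusted p = 0.000321, edgeR's quasi-likelihood test). Plk2 rose by 1.23 ± 0.08, Sesn2 by 0.69 ± 0.07, Gadd45a by 0.60 ± 0.06 and the anti-proliferative gene Btg2 by 0.55, while Tigar fell (-0.31). Of 23 members, 5 were higher, 1 was lower and 17 did not pass (8 and 1 passed when adjusted over the list alone), against 9 and 3 without Zfp335-deficient replicate 3. The median was 0.06, the camera adjusted p 0.0229, and with an estimated correlation the adjusted p was 0.171. Of 24 apoptosis regulators, the pro-apoptotic genes Bmf, Bid (-0.72 ± 0.07) and Bcl2l11 (-0.32 ± 0.07) and the caspase gene Casp9 (-0.27) fell, and the anti-apoptotic genes Bcl2a1b (0.62 ± 0.10) and Bcl2a1d (0.30), which are near-identical copies, rose. When adjusted over the list alone 4 were lower and 3 higher, and 18 members did not pass over all genes. Members lower and higher numbered 7 and 6 without Zfp335-deficient replicate 3, and without WT replicate 1, 2 or 3 they fell to 2 and 1. The Bcl2l11 call was lost without any WT library or Zfp335-deficient replicate 2 (range over all alternatives 6.76e-08 to 0.12). The list had a median of -0.01 and a camera adjusted p of 0.0756, and it passed at 0.0449 without WT replicate 3 (camera range over 15 alternatives 0.0449 to 0.325) and with fry (0.00587). Its mean of -0.26 lay below the median largely because of Bmf (-5.79 ± 0.15), and the list was not tested without Bmf.

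Some interferon-stimulated genes were lower in Zfp335-deficient cells, with 9 of 30 lower, 1 higher and 20 not passing (11 and 2 passed when adjusted over the list alone). Oas3, which makes the activator of RNase L, fell from 94.7 ± 2.68 to 73.2 ± 1.11 CPM (-0.37 ± 0.06, adjusted p = 0.00438, edgeR's quasi-likelihood test). Ifit1 fell (-0.51 ± 0.09), as did Rtp4 (-0.54 ± 0.09) and the RNA-sensor gene Dhx58 (-0.34 ± 0.06), while Isg15 rose (0.53). The median was -0.21, the camera adjusted p 0.00432, and with an estimated correlation the adjusted p was 0.171. Without Zfp335-deficient replicate 3, 21 were lower and 3 higher, and without WT replicate 1, 2 or 3 only 3 were lower. The calls for Ifit1 and Dhx58 were lost without WT replicate 2, that for Ifit1 also without WT 3 and that for Dhx58 without WT 1 (ranges over all alternatives 2.86e-05 to 0.052 and 1.59e-05 to 0.0687).

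The lamin A/C gene Lmna rose from 11.9 ± 0.636 to 20.3 ± 2.06 CPM (0.77 ± 0.09, adjusted p = 0.00158, edgeR's quasi-likelihood test). Lmnb1, a B-type lamin gene, rose by 0.28 ± 0.07, while Syne2, which links the nucleus to the cytoskeleton, fell (-0.49 ± 0.10). Both calls were lost without WT replicate 1, 2 or 3, and that for Lmnb1 also without Zfp335-deficient replicate 1 or 2 (ranges over all alternatives 3.57e-11 to 0.153 and 3.79e-05 to 0.0786). Ankle2, which encodes a nuclear-envelope assembly protein, was 56.9 ± 1.08 CPM in WT and 51.3 ± 5.34 CPM in Zfp335-deficient cells (-0.15 ± 0.08, adjusted p = 0.306), a difference that passed under no setting tried. Tbk1 (-0.37 ± 0.11, adjusted p = 0.0739) did not pass with all libraries but did without Zfp335-deficient replicate 1 (0.047) or 3 (0.000146; range over all alternatives 5.02e-06 to 0.239). Of 19 nuclear-lamina, nuclear-envelope and cytosolic DNA-sensing genes, 2 were higher and 1 lower, with the same counts when adjusted over the list alone, and 5 and 4 without Zfp335-deficient replicate 3. The camera adjusted p was 0.808, with a median of -0.01 and an upward direction in the test. None of the 16 H3K4-methyltransferase complex genes passed edgeR's quasi-likelihood test, over all genes or when adjusted over the list alone, and 0 had an unadjusted p under 0.05. DESeq2 and limma-voom called 0 as well, with 1 gene each at that unadjusted level. Leaving out Zfp335-deficient replicate 3, however, gave 1 higher and 3 lower, and with the length and GC correction as well 2 and 4. The list's median was -0.12 and its camera adjusted p 0.507, and the smallest p-values belonged to Kmt2b (-0.13 ± 0.06), Dpy30 (0.19 ± 0.08), Kmt2d (-0.41 ± 0.19) and Hcfc1 (-0.27 ± 0.13). Of these, Kmt2b and Hcfc1 passed without Zfp335-deficient replicate 3, at 0.011 and 0.0228 (ranges over all alternatives 0.0095 to 0.503 and 0.00782 to 0.515). Dpy30 and Kmt2d passed only with the correction as well (0.0327 and 0.00567; ranges up to 0.511 and 0.513).

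Of the metabolic lists, glycolysis genes had 3 of 19 members higher and none lower (4 and 0 when adjusted over the list alone). These were the monocarboxylate transporter genes Slc16a1 (0.51 ± 0.09) and Slc16a3 (0.51 ± 0.11) and the hexokinase gene Hk2 (0.50 ± 0.11), while Pfkp (0.19 ± 0.05) passed only without Zfp335-deficient replicate 3 (2.73e-05), in DESeq2 or with the length and GC correction (range over all alternatives 3.4e-07 to 0.23). All 3 calls were lost without WT replicate 1, which left none higher, and those for Slc16a3 and Hk2 without WT replicate 2 or 3 or Zfp335-deficient replicate 2 (ranges over all alternatives 5.38e-11 to 0.0525, 0.000983 to 0.0896 and 4.55e-11 to 0.116). The Hk2 call was also lost without Zfp335-deficient replicate 1. The list's camera adjusted p was 0.0451, and with an estimated correlation the adjusted p was 0.474. The call was lost without WT replicate 1 or 3 (adjusted p = 0.0589 and 0.0643), and without Zfp335-deficient replicate 3 it stood at 0.026 with 11 members higher (camera range over 15 alternatives 0.0212 to 0.0643). None of 35 nuclear-encoded respiratory-chain genes passed edgeR's quasi-likelihood test (camera adjusted p = 0.228, median 0.11; 0 when adjusted over the list alone). DESeq2 and limma-voom called 0 too, and 2 genes had an unadjusted p under 0.05 in edgeR. Leaving out Zfp335-deficient replicate 3 made 1 higher and 2 lower, the length and GC correction made 1 higher, and both together 4 higher and 3 lower. The list was led by Ndufv2 (0.22 ± 0.08), Cox5b (0.27 ± 0.11), Cox5a (0.21 ± 0.09) and Ndufb3 (0.18 ± 0.08), of which Cox5b passed at 0.0249 without Zfp335-deficient replicate 3 and Ndufv2 at 0.0137 with the correction as well (ranges over all alternatives 0.00467 to 0.399 and 0.0137 to 0.366). That list passed at 0.0482 without Zfp335-deficient replicate 1 and had the opposite direction, at 0.941, without Zfp335-deficient replicate 3. Of 13 mitochondrially encoded genes ND3 alone passed, over all genes and when adjusted over the list alone, and COX2 (0.21 ± 0.08), ATP6 (0.18 ± 0.11) and ND2 (-0.16 ± 0.10) did not. The camera adjusted p was 0.808, the median -0.07 and the mean 0.13.

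Cytosolic ribosomal-protein genes did not pass as a list with all libraries, with 1 of 33 higher and 2 lower over all genes and when adjusted over the list alone, and a camera adjusted p of 0.808. Across libraries they did vary together, with an estimated correlation between genes of 0.91. Their summed level was 28720 ± 825 CPM in WT and 27530, 27290 and 35280 CPM in Zfp335-deficient replicates 1, 2 and 3. Rps24 rose (1.26 ± 0.12), Rps9 fell (-1.23 ± 0.12) and Rpl30 fell (-0.82 ± 0.10), while Rpl3 (0.22 ± 0.09, adjusted p = 0.155) passed only without Zfp335-deficient replicate 3 (0.0164) or with the length and GC correction (range over all alternatives 0.00282 to 0.414). These values are uncertain because ribosomal-protein genes can share reads with processed pseudogenes. The median was 0.07, and without Zfp335-deficient replicate 3 the list had the opposite direction and passed, with 8 lower, 2 higher and an adjusted p of 0.0384 (camera range over 15 alternatives 0.0384 to 0.993).

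Markers of other cell types were mostly present at low levels, and none of their lists passed. Among neutrophil and monocyte genes, S100a9 rose from 5.97 ± 0.0984 to 10.8 ± 1.71 CPM and S100a8 from 2.75 ± 0.471 to 5.11 ± 1.25 CPM. Retnlg rose from 0.411 ± 0.148 to 0.952 ± 0.0938 CPM and Lyz2 from 2.29 ± 0.263 to 3.2 ± 0.185 CPM. These 4 of 12 monocyte, macrophage and neutrophil markers passed and none was lower (6 and 1 when adjusted over the list alone). Without WT replicate 2 or 3 or Zfp335-deficient replicate 2, S100a8, Retnlg and Lyz2 lost their calls and 1 member was higher, and 6 were without Zfp335-deficient replicate 3. S100a8 and Lyz2 also lost theirs without WT replicate 1, and Retnlg and Lyz2 without Zfp335-deficient replicate 1. For S100a8, Retnlg and Lyz2 the adjusted p ranged over all alternatives from 0.000724 to 0.111, 0.00639 to 0.112 and 0.0203 to 0.167. In camera the list had an adjusted p of 0.0889, and it passed without WT replicate 1 (0.0467) or Zfp335-deficient replicate 1 (0.0463), within a range of 0.0463 to 0.547 over 15 alternatives, and with fry (0.0338). Of 7 dendritic-cell and antigen-presentation markers, the class II genes H2-Aa (1.12 ± 0.082 and 2.45 ± 0.386 CPM), Cd74 (4.14 ± 0.441 and 7.67 ± 1.69 CPM) and H2-Eb1 (1.35 ± 0.174 and 2.11 ± 0.22 CPM) were higher, and 3 were when adjusted over the list alone. Without WT replicate 2 or 3 only 1 was, and Cd74 and H2-Eb1 lost their calls (ranges over all alternatives 3.06e-05 to 0.0702 and 0.0273 to 0.147). H2-Eb1 also lost its call without WT replicate 1 or Zfp335-deficient replicate 1 or 2. H2-Ab1 (0.57 ± 0.23 on the log2 scale) did not pass, and the camera adjusted p was 0.16.

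Among 8 natural-killer-cell markers, several of which effector CD8+ T cells also express, Klrb1c rose (0.55 ± 0.06), Klra9 and Klra8 fell (-0.94 ± 0.12 and -0.70 ± 0.11) and Klra3 (0.27 ± 0.07, adjusted p = 0.0518) did not pass. Without Zfp335-deficient replicate 3 Klra3 did, at 0.00902 (range over all alternatives 0.00113 to 0.184), and 2 markers were higher and 3 lower; 2 were higher without Zfp335-deficient replicate 1. The list's camera adjusted p was 0.587, and 3 members were higher and 4 lower when adjusted over the list alone. Of 8 B-cell markers, the immunoglobulin kappa gene Igkc rose from 4.64 ± 0.685 to 23.9 ± 2.31 CPM and Cd22 fell from 5.14 ± 0.295 to 1.98 ± 0.218 CPM (3 higher and 1 lower when adjusted over the list alone; 2 lower without Zfp335-deficient replicate 3). Cd79a (1.02 ± 0.37), below 1 CPM in both genotypes, did not pass, and the list's camera adjusted p was 0.57, with a median of -0.02 and a mean of 0.25. No member passed edgeR's quasi-likelihood test, over all genes or when adjusted over the list alone, among the 5 CD4 and regulatory T-cell markers (camera adjusted p = 0.943), which include Ikzf2 (0.62 ± 0.25) and Cd4 (-0.56 ± 0.34, at 0.35 and 0.236 CPM). None passed either among the 3 gamma-delta T-cell markers (camera adjusted p = 0.943; Trgc2 0.51 ± 0.17) and the 9 erythroid markers (camera adjusted p = 0.293; Car2 -0.40 ± 0.12, Hbb-bs -0.22 ± 0.13). In each of these 3 lists 1 gene had an unadjusted p under 0.05 in edgeR, and DESeq2 and limma-voom called 0. However, 5 erythroid markers were lower and 1 CD4 or regulatory T-cell marker was higher without Zfp335-deficient replicate 3, among them Car2 (0.026), Hbb-bs (3.05e-05) and Ikzf2 (1.57e-05). Over all alternatives these ranged from 0.0178 to 0.238, 6.14e-06 to 0.604 and 4.99e-06 to 0.351. With the length and GC correction 3 erythroid markers were lower, and 1 marker of each of the other 2 lists was higher, with Trgc2 at 0.0443 (range over all alternatives 0.0443 to 0.289). Only 2 platelet markers were measured, too few for the list test, and of these Itgb3 rose (0.41 ± 0.08; not called without WT replicate 1 or 3, range over all alternatives 0.000117 to 0.0643) and Itga2b (0.06 ± 0.12) did not pass.

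Over the 17 lists of T cell biology, 6 passed camera with its preset correlation, namely the mitotic, S-phase, cytotoxic, interferon, p53 and glycolysis lists, and none held with an estimated correlation, where 4 had an unadjusted p under 0.05. The mitotic list did hold with it in 3 of 15 alternatives, at 0.0476 without Zfp335-deficient replicate 3. With fry, which asks whether a list's genes move on balance in a single direction and not whether they differ from other genes, 8 passed. Among the 10 ways to split the 6 libraries into equal groups, 7 gave at least 6 lists with the preset correlation. The number of lists passing with it therefore does not set the genotypes apart. Of the 8 other-cell and handling lists tested, the immediate-early and heat-shock list alone passed. With an estimated correlation it held, and in 5 of 15 alternatives, but not with any 1 library left out (0.0534 to 0.132).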

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

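The length and GC correction, its combination with a left-out library and the removal of enriched bins were chosen after seeing the data. The lower Zfp335 level kept its direction and stayed past the threshold under all alternatives that tested it against no change, with log2 fold changes from -0.72 to -0.65 and adjusted p from 1.23e-16 to 0.00673, but it did not pass against a 1.5-fold change (0.589). Of 128 named genes, none changed direction and 85 kept their side of the 0.05 threshold under every alternative that tested them against no change. Of the 90 called, 33 passed the test against a 1.5-fold change, which Tcf7 did not, and 71 passed a threshold of 0.01. Most of the others lost their call with fewer libraries (18, 21 and 21 genes without WT 1, 2 and 3) or gained it without Zfp335-deficient replicate 3 (16 genes). Replicate spread limits small changes more than depth does, and 10% of simulated 1.25-fold changes were recovered.

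The 1622 changed genes (983 higher, 639 lower) became 2966 (1580 higher, 1386 lower) with the length and GC correction, 4608 (2287 higher, 2321 lower) with that correction and without Zfp335-deficient replicate 3, 289 (177 and 112) when tested against a 1.5-fold change and 789 (508 and 281) at an adjusted p threshold of 0.01. With 1 library left out the count ran from 805 (without WT 2) to 4112 (without Zfp335-deficient 3), with 521 to 2122 higher and 284 to 1990 lower; it was 824 and 810 without WT 1 and 3 and 1040 without Zfp335-deficient 2. Of the 1622 genes, 1614 were among the 4112. Lower counts follow in part from fewer samples, and otherwise the cause was not tested. DESeq2 called 1947 genes, limma-voom 1603, and other scalings and filters 1234 to 1621.

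With the replicate block 876 genes were called (568 higher, 308 lower), and 2 other-cell lists. Correlations of the deviations of same-numbered libraries from their group means were -0.102, -0.007 and -0.211, and no library correlated best with its own number. Replicate 3 dominates the deviations within the Zfp335-deficient group, so these correlations cannot decide whether same-numbered libraries shared a recipient. The block also ended the glycolysis call (0.0573).

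With an estimated correlation in camera 0 of the 6 biology lists passed (4 at an unadjusted p under 0.05), and with fry 8 passed. With that correlation the mitotic list passed with upper-quartile scaling (0.0274), with the length and GC correction (0.0185) and without Zfp335-deficient 3 (0.0476), and the immediate-early list (0.0453) did not with the block (0.303), those 2 settings (0.223 and 0.104) or any 1 library left out (0.0534 to 0.132). Of the other-cell lists 3 passed with fry, 2 without WT 1 and 2 without Zfp335-deficient 1, against 1 (range 1 to 2 with 1 library left out); the list added was that of monocytes, macrophages and neutrophils, with fry also that of dendritic cells. The stricter filter ended the glycolysis call (0.0507). Some lists changed direction, with these adjusted p and ranges with 1 library left out. Without Zfp335-deficient 3 they were the ribosomal-protein (0.0384; range 0.0384 to 0.992), respiratory-chain (0.941; 0.0482 to 0.941), CD4 (0.845; 0.83 to 0.965) and gamma-delta lists (0.975; 0.83 to 0.975). Without WT 3 they were the ribosomal-protein (0.992), adhesion (0.992; 0.34 to 0.995) and gamma-delta lists (0.949), and without Zfp335-deficient 1 the T cell receptor list (0.985; 0.442 to 0.995). Further changes of direction were, with the length and GC correction, ribosomal-protein 0.445 and CD4 0.897, and, with receptor segments left out, B-cell 0.338, a setting that removes Igkc. Other than that, the cause was not tested.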

Other observations

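The tests of transcript length, of reads shared between copies and of coordinated regulation of neighbours below were chosen only after the results they bear on were seen. Antigen-receptor segments differed between the genotypes. Trbv12-1 rose from 306 ± 17.1 to 618 ± 28.7 CPM (log2 fold change 1.02 ± 0.07, adjusted p = 8.22e-05, edgeR's quasi-likelihood test, n = 3 each), and Trav14d-1 from 131 ± 4.86 to 261 ± 17.4 CPM (0.99 ± 0.07, adjusted p = 9.71e-05). These were the most abundant beta and alpha variable segments measured in both genotypes. Of the 30 alpha segments tested, Trav14d-1 alone rose and 10 fell, among them Trav21-dv12 (-1.01 ± 0.13) and Trav19 (-1.25 ± 0.17), at far lower levels of 10.2 and 3.34 CPM in WT. Trbv12-1 and Trav14d-1 belong to the segment families of the OT-I receptor, which recognises an ovalbumin peptide, but the labels do not say which receptor the transferred cells carried. Variable segments are similar to each other, so reads may be assigned to the wrong member, which was not tested; leaving out receptor segments, haemoglobin and mitochondrial genes left 1582 genes called.

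Zfp335-deficient replicate 3 differed from replicates 1 and 2. A candidate explanation is lower RNA integrity, which the labels do not report per library. Its deviation fell with transcript length (Spearman's rho -0.515 across genes). Over the 8477 genes of log2 CPM 3 or more, a correction for length and GC content removed 54.5% of the variance of this deviation. Its SD went from 0.33 to 0.222 on the log2 scale, against 0.105 between replicates 2 and 1. The correction was fitted to these same libraries, so the share removed is the same trend and not separate support for that explanation. GC content followed the deviation as closely (rho 0.518), but also the difference of replicates 2 and 1 (0.238, against -0.052 for length), and length and GC were not separated. As for other cells, no list of their markers with a summed level of at least 10 CPM exceeded 1.31 times the mean of replicates 1 and 2. This cannot exclude them, because abundant members of a list can hide a rise in scarce ones. The monocyte, macrophage and neutrophil list summed to 1320 CPM in WT, where S100a9 and S100a8 were at 5.97 and 2.75 CPM. No biological explanation was tested.

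Genes changed at least 2-fold lay near each other in the genome more often than matched genes, and 18 of them were pseudogenes. Of the 374 genes changed at least 2-fold, 348 had a position outside the immunoglobulin and T cell receptor loci, and 190 of these lay within 1 Mb of another, against a median of 145 (range 105 to 184) in 10000 draws of genes matched on expression (permutation p = 1e-04, one-sided, the smallest these draws can give), and 15 of 55 tested genes at 120 to 125 Mb of chromosome 2 were among them (8 higher, 7 lower). Stretches of another strain's genome, with variants that change expression or mapping, are a candidate explanation, as are reads that move between near-identical copies. As to copies, 10.8% of 167 pseudogenes and 2.96% of 11941 other genes with a position, receptor loci included, changed at least 2-fold (odds ratio 3.96, Fisher's exact test, two-sided p = 3.58e-06). Slc28a2 (-2.69) and Slc28a2b (2.49), and Tgtp1 (-1.87) and Tgtp2 (1.48), moved apart. Yet Slc28a2 fell from 186 ± 4.27 to 28.7 ± 0.2 CPM, and Slc28a2b rose only from 1.75 ± 0.467 to 9.77 ± 0.454 CPM. Tgtp1 fell from 32.5 ± 0.905 to 8.89 ± 0.953 CPM, and Tgtp2 rose from 28.2 ± 0.856 to 78.8 ± 4.28 CPM. An exchange of reads within either pair therefore does not account for the whole change. Of 282 neighbouring pairs 53.5% moved the same way, against a median of 51.1% with shuffled directions, which is no clear excess (permutation p = 0.253, one-sided). That test cannot decide on coordinated regulation of neighbours, because its pairs include near-identical copies that moved apart, such as Tgtp1 and Tgtp2. An effect of Zfp335 itself on the genes changed at least 2-fold stays open. The labels name C57BL/6 for both genotypes, but Nnt, which the C57BL/6J substrain lacks in part and which was chosen after its values were seen, fell from 26.8 ± 0.931 to 9.28 ± 3.95 CPM (-1.53 ± 0.28, adjusted p = 0.0104), and without the enriched bins 1546 genes were called.

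Immunoglobulin transcripts were higher in Zfp335-deficient libraries, with 14 of 23 genes and segments whose symbols start with Igh, Igk or Igl higher and none lower. They were counted by symbol, which can take in a gene that is not an immunoglobulin gene. Igha rose from 4.56 ± 0.175 to 45 ± 8.23 CPM (3.30 ± 0.14) and Jchain from 1.39 ± 0.316 to 7.01 ± 1.05 CPM (2.34 ± 0.19), whereas Ighm did not pass (51.6 ± 1.86 and 50.3 ± 3.31 CPM). B cells or plasma cells that passed the CD8+ sort, which should remove them, or their free RNA, are a candidate explanation that cannot be told apart from others. B-cell markers other than immunoglobulin genes summed to 12 ± 0.292 CPM in WT and 8.24 ± 0.785 CPM in Zfp335-deficient libraries, but Cd22 made up most of that fall, and Cd79a (1.02 ± 0.37, below 1 CPM) was too low to decide. The 4 measured plasma-cell markers, a list added after the data were seen, were 1.22-fold higher (66.6 ± 1.58 and 81.5 ± 3.19 CPM). Most of that sum is Xbp1, which T cells also express (64.6 and 73.3 CPM), so it hides changes in the scarcer markers. These were Jchain, which rose as given above, Sdc1 (0.357 ± 0.114 and 0.805 ± 0.213 CPM) and Derl3 (0.242 ± 0.0738 and 0.341 ± 0.112 CPM). The rise of Jchain goes with plasma cells, but Jchain is itself part of the pattern to be explained. Sdc1 and Derl3 were higher too, but did not pass and were below 1 CPM, too low to decide.

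With 3 libraries against 3 there are 10 ways to split the samples, too few for a share under 0.05. The real split gave 1622 changed genes and was 1 split of 10 with as many, the highest of the others being 0 in edgeR's test, with 44 to 574 genes at an unadjusted p under 0.05. For the biology lists the real split gave 6, 7 of the 10 splits gave as many, and the highest other gave 8. For the other-cell lists the real split gave 1, 9 of the 10 gave as many, and the highest other gave 2.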
